A study of Mus musculus with 4 samples.

How the data were processed

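RNA sequencing measured gene expression in 4 libraries of mouse bone marrow-derived macrophages, all stimulated with the bacterial cell wall component lipopolysaccharide (LPS). Of these, 2 libraries came from cells given a control morpholino (Ctrl MO) and 2 from cells given morpholinos against Regnase-1 (Reg1-MOs). Morpholinos are synthetic antisense oligomers that bind RNA without recruiting RNase H. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate mice or cultures, so p-values here measure only the spread between these libraries, which may be technical.

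Poly(A) RNA was made into directional libraries with a NEBNext Ultra II kit and read on a NextSeq 500, per the labels' protocols. Per the submitters' processing notes, cutadapt, FastQC, HISAT2 1.6.3 and the mouse build mm10 were used; the order of these steps, the read counter, its strand setting, the gene filter and the normalization are not given in the sources used here. The authors deposited 1 table of 11111 genes with 1 column of log2 values per library. In each column, 2 to the power of the value, divided by the column's smallest step and less an offset of 0.5, came out within 0.01 of a whole number for 100% of the genes. The deposited values are therefore log2 of (reads + 0.5) times a constant per library, and the reads per gene could be recovered. The reads in the table summed to 24904180 and 25213695 for the Ctrl MO libraries and 24652918 and 23369753 for the Reg1-MOs libraries. The library sizes that the scale implies were smaller, at 19074804, 19058462, 19377000 and 17767798, a ratio of 1.27 to 1.32, so a scaling other than the plain total was applied; which one is not stated. The Reg1-MOs columns are headed MO1 and MO2, which are also the names the labels give the 2 targeting morpholinos. Whether each of these libraries received 1 morpholino or both is not settled by the labels, and the 2 were treated as replicates of 1 group, as their titles number them.

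Of the 11111 rows, 6 carried no symbol and 21 no Ensembl identifier. Of 11090 identifiers, 11088 were found in the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and 10927 had the same symbol there. Positions are given from that annotation, counted from 1. Reads shared between near-identical genes can have been split or dropped by the unstated counting. Values for genes such as Gapdh, Fth1, Ftl1, Prdx1, Txn1, Ifit3 and Ifit3b are therefore uncertain. Gapdh, for example, was listed with 7 to 13 reads per library.

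The test was limma's moderated test with a mean-variance trend (limma 3.58.1, statmod 1.5.0, R 4.3.3), two-sided, on the deposited log2 values of all 11111 genes with group as the only term. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. The plan, fixed before the data were examined, had assumed linear normalized counts. For values already on a log scale it laid down that they be used as deposited and unfiltered, which was done. All fold changes are Reg1-MOs over Ctrl MO with 2 libraries per group, and SE is the moderated standard error of the log2 fold change. The prior added 5.47 degrees of freedom to 2 residual ones.

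The genes named follow a rule fixed with that plan. They are Zc3h12a, which encodes Regnase-1; Il6, Il12b, Ptgs2, Nfkbiz, Tnf, Il1b and Cxcl1; the 8 largest rises and the 8 largest falls among genes past the threshold; and in each gene list the 2 members with the smallest p. Predicted genes, RIKEN clones and numbered pseudogenes were left out of the largest changes. The rule's minimum, a mean deposited value of at least 50, was applied to the recovered reads, since the deposited values are logs. It gave 63 genes, not all of which are reported here; the other 78 genes named below were chosen after their values were seen.

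The plan also fixed 25 gene lists. They were Regnase-1 target transcripts named in earlier literature, inflammatory cytokines, chemokines, NF-kappaB genes, type I interferon response, RNA-binding regulators of mRNA decay, Toll-like receptor 4 signalling, immediate early genes, classical macrophage activation effectors, alternative macrophage activation, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, lysosome and TFEB targets, glycolysis and hypoxia, iron handling, cell cycle and macrophage identity. Markers of neutrophils, dendritic cells and antigen presentation, lymphocytes, stromal cells and fibroblasts, mast cells and basophils, and erythroid cells, and the mitochondrially encoded transcripts, completed the set. Lists with at least 4 members in the table, 22 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22. Each was also tested with camera at an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. With an estimated correlation camera draws on the 2 residual degrees of freedom. A call lost there can therefore stem from the few libraries as well as from correlation.

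The procedure was tested on simulated reads for all 11111 genes, in 10 runs. In each run 200 genes were changed, all with a mean of at least 50 reads. The procedure recovered 7.2% of genes changed 1.25-fold, 55.6% of those changed 1.5-fold, 89.4% of those changed 2-fold and 99.8% of those changed 4-fold. Of its calls, 7.49% were false. Of 10 simulated lists shifted by 0.5 on the log2 scale, camera called 10, and it called 1 of 188 unshifted ones. Simulated genes varied independently of one another, whereas the estimated correlation of real lists reached 0.556 (chemokines). The 1 of 188 is therefore no false-call rate for lists whose genes vary together. Alternatives were other offsets, filters on low reads, scalings and variance models, a replicate term, leaving out each library, and voom weights on the recovered reads, the last chosen after the data were seen. edgeR and DESeq2 were not run, although they were planned if whole reads could be recovered and that condition was met, because tests of counts were ruled out here for values deposited as logs. This departs from the plan, and voom weights stood in for them. Figures and annotation steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.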

Results

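Transcript levels were measured by RNA sequencing in macrophages grown from the bone marrow of C57BL/6 mice over 7 days, with a change of medium on day 4. The cells received a control morpholino or Regnase-1-targeting morpholinos at 2 µM with the delivery peptide Endoporter (6 µl/ml) for 24 hours, and then LPS at 10 ng/ml for 4 hours. There were 2 libraries per group, with 23369753 to 25213695 reads each in the table and a median of 404 to 437 reads per gene. The 10 most abundant genes held 7.63% to 8.52% of the reads. The replicates differed by more than counting noise, with a chi-square per degree of freedom of 4.25 between the Ctrl MO libraries and 15.2 between the Reg1-MOs libraries, against 39.4 to 64.7 between groups. Across genes, which are not independent replicates, Pearson's r was 0.995 between the Ctrl MO libraries, 0.994 between the Reg1-MOs libraries and 0.986 to 0.988 between groups.

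The comparison asks which transcripts of LPS-stimulated macrophages differ when Regnase-1 is targeted. Regnase-1 is an RNase that degrades inflammatory mRNAs, and its own mRNA, by way of stem-loops in their 3' untranslated regions, and the Reg1-MOs were designed to keep it from degrading its own mRNA. With Reg1-MOs, Zc3h12a, the Regnase-1 gene, was 2.14-fold higher, and the haem-degrading enzyme Hmox1 was 16.1-fold higher. The cytokine gene Il6 was 1.86-fold lower, while the neutrophil chemoattractant gene Cxcl1 was 2.91-fold higher. Lysosomal and glycolytic genes were higher as lists, and inflammatory cytokines, cholesterol synthesis genes and stromal cell markers were lower as lists by camera with a preset correlation, and none of these lists passed with an estimated one (lowest adjusted p = 0.314). Of 11111 genes, 691 rose and 670 fell by limma at an adjusted p of 0.05, 12.2% of the table. The median size of these changes was 0.53 on the log2 scale, and 89 genes rose and 127 fell by at least 2-fold.

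Zc3h12a (ENSMUSG00000042677; chromosome 4, 125118423 to 125127840 on GRCm38, minus strand) had 3407 and 3572 reads with Ctrl MO and 7799 and 6753 with Reg1-MOs, a log2 fold change of 1.10 (SE 0.07, limma adjusted p = 4.008e-04). Among the 7 genes fixed with it, Cxcl1 rose by 1.54 (SE 0.08, adjusted p = 1.26e-04). Il6 fell by 0.89 (SE 0.07, adjusted p = 0.00103), Nfkbiz, an atypical NF-kappaB inhibitor family member, fell by 0.54 (SE 0.07, adjusted p = 0.00387) and Il1b fell by 0.33 (SE 0.08, adjusted p = 0.0299). Tnf stood at 0.11 (SE 0.07, adjusted p = 0.299), Il12b at -0.32 (SE 0.10, adjusted p = 0.0807) and the prostaglandin synthase Ptgs2 at -0.27 (SE 0.14, adjusted p = 0.232). The Il1b call ended without any 1 of the 4 libraries, with quantile normalization (adjusted p = 0.125) and without a variance trend. That of Nfkbiz also ended without a variance trend (adjusted p = 0.0605). Without Reg1-MOs replicate 2, Il12b (adjusted p = 0.0364) and Ptgs2 (-0.51, adjusted p = 0.0262) passed, and without Reg1-MOs replicate 1 they stood at -0.18 and -0.04. Tnf stood at 0.07 without Ctrl MO replicate 2.

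**Figure D1:**
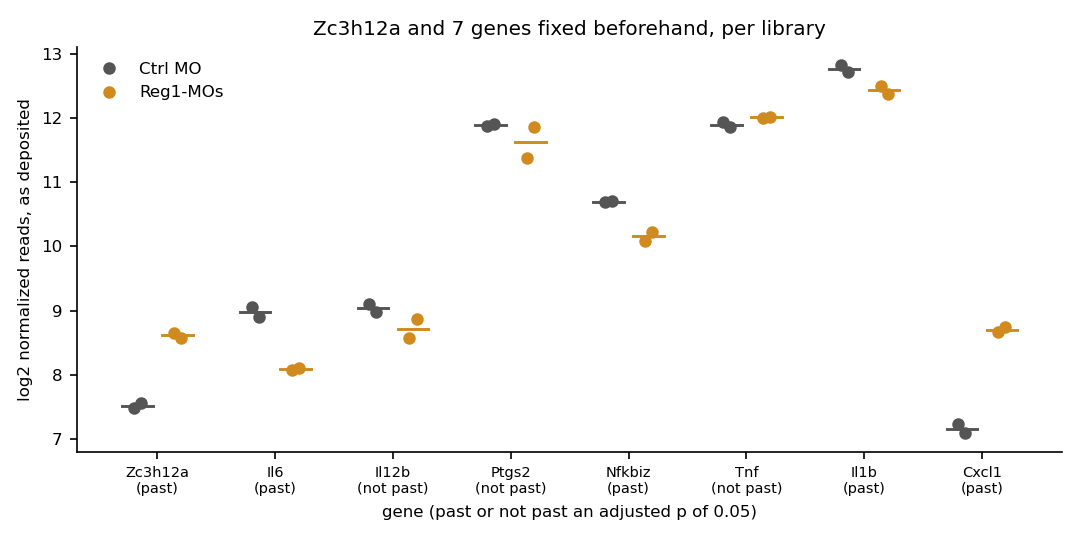
Deposited log2 normalized reads (vertical axis) of Zc3h12a and the 7 genes fixed with it, per library; points are libraries, 2 per group, and bars are group means. Zc3h12a and Cxcl1 were higher in both Reg1-MOs libraries than in both Ctrl MO libraries, by 1.10 and 1.54, and Il6 was lower in both, at -0.89.

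The list of Regnase-1 target transcripts named in earlier literature moved both ways. Of its 13 members in the table, 4 rose and 3 fell (4 and 4 adjusted over the list alone). The chemokine genes Cxcl1, Cxcl3 (1.00) and Cxcl2 (0.45) and the NF-kappaB inhibitor family gene Nfkbid (0.82) rose, while Il6, Nfkbiz and the interleukin-2 receptor chain Il2ra (-1.20) fell. Il12b, Ptgs2, Lcn2 (-0.25), Irf4 (0.58), the transferrin receptor Tfrc (-0.21) and Rel (-0.19) did not pass in the main fit. With a replicate block, a pairing that no label states, the list had 5 rises and 8 falls. Without Reg1-MOs replicate 1 or replicate 2, in this order, Rel stood at 0.18 and -0.56, Lcn2 at -0.40 and -0.10, and Irf4 at 0.89 and 0.27, and Tfrc stood at -0.11 without Reg1-MOs replicate 1. Without either control, Rel stood at -0.32 (replicate 1 left out) and -0.06 (replicate 2 left out). The median was -0.21 and the mean 0.04, so these differ in sign, and camera gave an adjusted p of 0.932 (down, but up without Reg1-MOs replicate 1 or either control). The median was -0.04 without Reg1-MOs replicate 1. The fry test for change in either direction gave an adjusted p of 0.00202, and it called 21 of the 22 lists tested. Without Reg1-MOs replicate 1 the calls of Cxcl3 (limma adjusted p = 0.0657) and Cxcl2 (adjusted p = 0.0554) ended, and that of Cxcl2 also without Ctrl MO replicate 2 (adjusted p = 0.0928). The list had 2 rises without Reg1-MOs replicate 1, 5 falls without Reg1-MOs replicate 2, and 2 of each without a variance trend.

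Among genes with a mean of at least 50 reads, the largest rises after Hmox1 (log2 fold change 4.01, SE 0.09; 1779 and 1825 reads against 32264 and 24808; limma adjusted p = 2.668e-06) included those of the cyclin-dependent kinase inhibitor Cdkn1c (2.86, SE 0.10) and the integrin chain Itgb7 (2.68, SE 0.10). Others were the iron exporter Slc40a1 (2.44, SE 0.10), the ubiquitin hydrolase Uchl1 (2.34, SE 0.18), the transporter Slc43a3 (2.25, SE 0.17) and the NADPH-producing malic enzyme Me1 (1.86, SE 0.15). The largest falls at that level were those of the integrin chain Itgad (-3.75, SE 0.20), the collagen genes Col12a1 (-2.47, SE 0.24) and Col5a1 (-1.92, SE 0.20), the prostaglandin-degrading Hpgd (-2.07, SE 0.22), Cyp1b1 (-1.93, SE 0.19), the basement membrane gene Nid1 (-1.91, SE 0.20), the collagen chaperone Serpinh1 (-1.88, SE 0.16) and the potassium channel Kcna2 (-1.88, SE 0.20). These falls were measured in genes with means of 50.5 to 168.5 reads. Stromal and fibroblast markers were lower in the same libraries, with a list median of -1.40. All of the named rises and falls in this group stayed past the threshold with any 1 library left out, with adjusted p up to 0.0353.

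**Figure D2:**
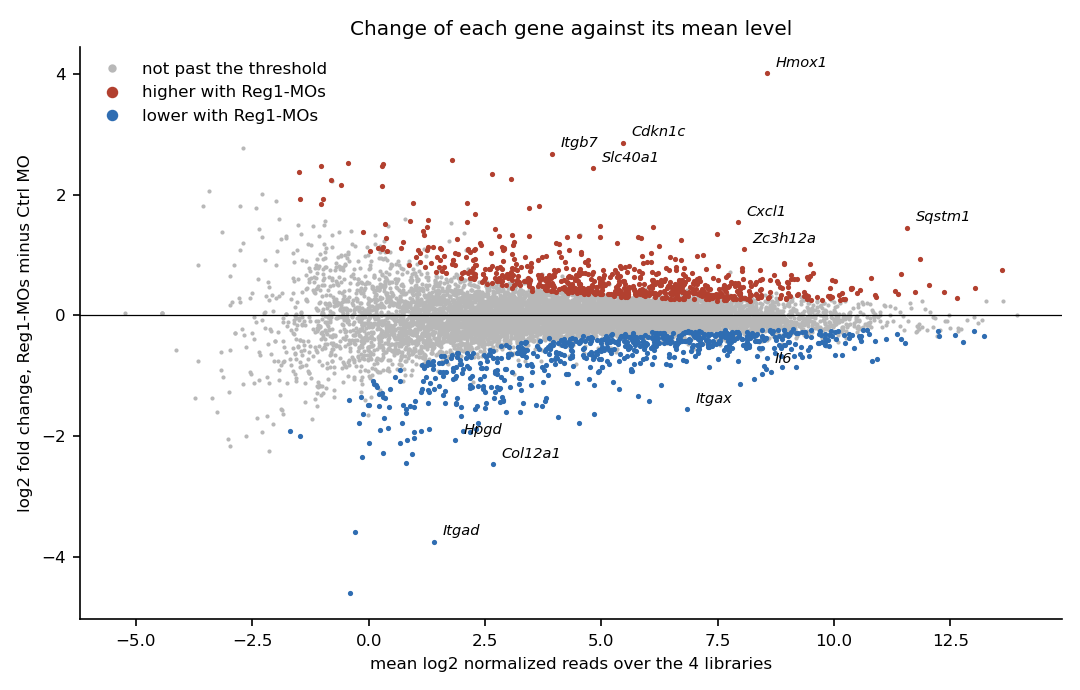
Log2 fold change of each of 11111 genes, Reg1-MOs minus Ctrl MO (vertical axis), against its mean log2 normalized reads over the 4 libraries (horizontal axis); red points rose and blue points fell at an adjusted p of 0.05, and grey points did not pass. Hmox1 at 4.01 stands highest among the labelled genes and Itgad at -3.75 lowest.

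Itgad lies beside 2 other genes for integrin alpha chains of the beta-2 family on chromosome 7, and all 3 fell. Itgam, encoding CD11b (128062640 to 128118491), fell by 0.67 (SE 0.08). Itgax, encoding CD11c (128129547 to 128150657), fell by 1.55 (SE 0.07; 3644 and 3850 reads against 1328 and 1168). Itgad, encoding CD11d (128154376 to 128223816), had 180 and 191 reads against 12 and 14. Among the 7 other genes of the table that reach within 100000 bp of these 3, the inflammasome adaptor gene Pycard fell by 0.31 (limma adjusted p = 0.0360) and the other 6 did not pass. The Pycard call ended without any 1 of the 4 libraries and without a variance trend. That of Itgam also ended without a variance trend (adjusted p = 0.0585).

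**Figure D3:**
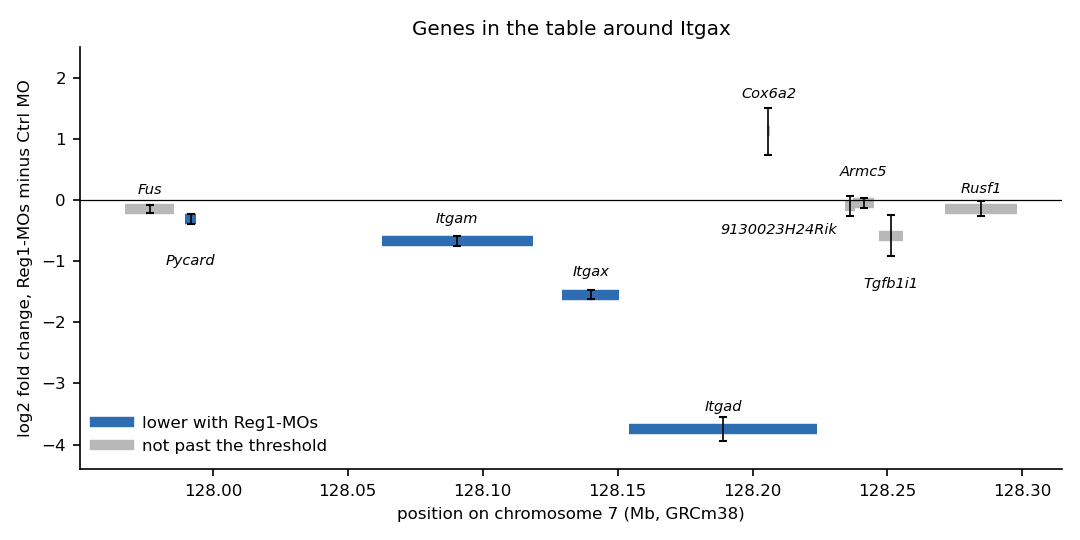
Log2 fold change, Reg1-MOs minus Ctrl MO (vertical axis), of the genes of the table around Itgax, drawn over their extent on chromosome 7 in Mb of GRCm38 (horizontal axis); whiskers are 1 SE, from 2 libraries per group. Itgam, Itgax and Itgad lie side by side at -0.67, -1.55 and -3.75.

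Inflammatory cytokines were lower as a list. Of 18 members, 9 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 0.00402; the adjusted p was 0.314 with an estimated correlation. Besides Il6, the genes of the cytokine IL-27, Ebi3 (-0.62) and Il27 (-0.54), and Il18 (-0.58) fell, while Il23a, encoding the IL-23 subunit p19, rose by 1.31 (SE 0.12, limma adjusted p = 0.00139). The cytokine falls were 5 without Ctrl MO replicate 1 or Reg1-MOs replicate 1, and 2 beside 2 rises without a variance trend, where the calls of Ebi3 (adjusted p = 0.0527) and Il27 (0.0580) ended. Among 20 chemokines, 3 rose, namely Cxcl1, Cxcl3 and Cxcl2, and 7 fell (5 and 10 adjusted over the list alone). Ccl22 (-1.05), Ccl24 (-1.53) and the interferon-induced Cxcl9 (-0.67; adjusted p = 0.0845 without a variance trend) were among the falls. Chemokine falls were 4 without Ctrl MO replicate 1, 4 beside 1 rise without Reg1-MOs replicate 1, 3 without Reg1-MOs replicate 2 and 2 beside 1 rise without a variance trend. The chemokine list did not pass camera (adjusted p = 0.147), and did without Ctrl MO replicate 2 (0.0149) or Reg1-MOs replicate 1 (0.0415). Stromal cell markers, at a median of -1.40, fell in the same libraries.

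Classical activation effectors were also lower as a list, with 3 rises and 5 falls among 21 members (5 and 9 adjusted over the list alone), a median of -0.25 and a camera adjusted p of 0.0188 (adjusted p = 0.314 with an estimated correlation, and 0.0732 without a variance trend). The median was -0.165 without Reg1-MOs replicate 1. The scavenger receptor Marco (-0.90), the histamine-producing Hdc (-0.74), the formyl peptide receptor Fpr2 (-0.55) and Edn1 (-0.47) were among the falls, and Slpi (0.97), the lectin Clec4e (0.44) and Ptges (0.36) rose. Nos2 stood at -0.30 (adjusted p = 0.0549, and 0.0338 without Reg1-MOs replicate 2; -0.20 without Reg1-MOs replicate 1) and Acod1 at -0.13 (adjusted p = 0.237). Of 14 genes of alternative activation, the transcription factor Klf4 (2.46-fold) rose and Ccl22, Ccl24, the mannose receptor Mrc1 (-0.70) and the scavenger receptor Cd163 (-4.60, and -3.60 without Reg1-MOs replicate 1 or -5.60 without Reg1-MOs replicate 2 or -2.83 with an offset of 8 reads; 71 and 71 reads against 1 and 5) fell (2 and 5 adjusted over the list alone). That list had a camera adjusted p of 0.156, and 0.0188 without Ctrl MO replicate 2. Leaving out 1 library ended the calls of Ptges (adjusted p up to 0.246) for either control or Reg1-MOs replicate 1, of Clec4e for Ctrl MO replicate 2 (0.0553) and of Slpi for Reg1-MOs replicate 1 (0.102). Classical effectors had 1 rise without Ctrl MO replicate 2 or Reg1-MOs replicate 1, and had 8 falls without Reg1-MOs replicate 2. Without a variance trend they had 0 rises and 2 falls, and the calls of Hdc (limma adjusted p = 0.0529), Edn1 (0.08455), Mrc1 (0.0657) and Cd163 (0.0575) ended. Stromal cell markers, with a list median of -1.40, were lower in the same libraries.

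Among 33 genes of the type I interferon response, 6 fell and Ifit3b (0.54) and Ifit3 (0.30) rose (9 and 3 adjusted over the list alone). The list median was -0.145 with a camera adjusted p of 0.0128 (adjusted p = 0.44 with an estimated correlation). The median was -0.0905 without Reg1-MOs replicate 1. The call ended with quantile normalization (median -0.0946, adjusted p = 0.0525), without Ctrl MO replicate 1 (0.0613) and without Ctrl MO replicate 2 (0.0732). The RNA sensor Ifih1 fell by 0.46, and Isg15 stood at 0.05 (limma adjusted p = 0.698), and at -0.01 without Reg1-MOs replicate 1. The Ifih1 call ended without Ctrl MO replicate 2 or Reg1-MOs replicate 1 (adjusted p up to 0.0564) and the Ifit3 call without either control or Reg1-MOs replicate 1 (up to 0.257). The interferon list had 1 fall and 1 rise without either control, 0 falls and 1 rise without Reg1-MOs replicate 1, and 0 of both without a variance trend (Ifit3b at an adjusted p of 0.0585). The median of the stromal cell markers in the same libraries was -1.40.

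Lists of signalling and regulatory genes did not pass camera. Of 22 NF-kappaB genes, Nfkbid and Nfkbib (0.28) rose and Tnip3 (-0.66) and Nfkbiz fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.256). Of 21 genes of Toll-like receptor 4 signalling, the adaptor Traf3 (0.59) rose and the co-receptor Ly96 (-0.44) and Ticam2 (-0.38) fell (1 and 2 adjusted over the list alone; 0.643), with Tlr4 itself at 0.35 (limma adjusted p = 0.141, and 0.0371 without Reg1-MOs replicate 1; 0.12 without Reg1-MOs replicate 2). Of 17 immediate early genes, Ier3 (0.52) and Fos (0.41) rose and Dusp2 (-0.34), Ier2 (-0.45) and Myc (-0.46) fell (4 and 7 adjusted over the list alone; 0.643). Of 18 RNA-binding regulators of mRNA decay, Zfp36l2 (0.88), Zfp36l1 (0.44) and the Regnase family member Zc3h12d (0.47) rose and none fell (4 and 3 adjusted over the list alone; 0.932), with a median of -0.06 against a mean of 0.05 (median -0.03 without Reg1-MOs replicate 1 and -0.10 without Reg1-MOs replicate 2, where camera's direction was down). Of 19 p53 targets, Mdm2 (0.74) and Plk2 (0.63) rose and Bbc3 (-0.41) fell (2 and 5 adjusted over the list alone; 0.291), and Cdkn1a stood at 0.00 (adjusted p = 0.991). Of 19 genes of the unfolded protein and integrated stress response, 8 fell, among them the chaperone genes Hyou1 (-0.43), Sdf2l1 (-0.63) and Hspa5 (-0.24), and Ddit3 (0.47), Phgdh (0.45) and the cystine transporter Slc7a11 (0.33) rose (9 and 4 adjusted over the list alone; 0.103, and 0.0415 without Reg1-MOs replicate 1). Among these genes, Nfkbid, Tnip3, Nfkbiz, Traf3, Zfp36l2, Mdm2 and Plk2 passed with any 1 library left out, but Nfkbiz (adjusted p = 0.0605), Traf3 (0.0685) and Zfp36l2 (0.0595) did not pass without a variance trend. Without any 1 library the calls ended of Nfkbib (limma adjusted p up to 0.419), Fos (0.258), Myc (0.246), Zfp36l1 (0.238), Bbc3 (0.1999), Hspa5 (0.413) and Phgdh (0.2245). Those of Ly96 (up to 0.0977), Ticam2 (0.124), Dusp2 (0.2025) and Ddit3 (0.0741) ended without either control or Reg1-MOs replicate 1, and those of Ier3 (0.121) and Hyou1 (0.1105) without Ctrl MO replicate 2 or Reg1-MOs replicate 1. Those of Ier2 (0.143) and Zc3h12d (0.202) ended without Ctrl MO replicate 1 or either Reg1-MOs library, that of Sdf2l1 (0.0746) without either Reg1-MOs library, and that of Slc7a11 (0.210) without either control or Reg1-MOs replicate 2. The 8 falls of the stress response list were 2 without Ctrl MO replicate 1 or Reg1-MOs replicate 2 and 1 without Ctrl MO replicate 2 or Reg1-MOs replicate 1, and its 3 rises at most 1. With equal totals that list had 4 rises and 4 falls, and the calls of Hspa5 (limma adjusted p = 0.05007, and 0.185 with quantile normalization) and Myc (0.0505) ended. Without a variance trend the lists of the stress response, immediate early genes, Toll-like receptor 4 signalling and mRNA decay had 0 rises and 0 falls. Without Reg1-MOs replicate 2 there were 4 falls among NF-kappaB genes, 2 among regulators of mRNA decay and 2 among p53 targets, and without Reg1-MOs replicate 1 there were 2 rises in Toll-like receptor 4 signalling.

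Lysosomal and TFEB target genes were higher as a list: 12 of 26 rose and Lamp2 (-0.37) fell (15 and 1 adjusted over the list alone), with a median of 0.24 and a camera adjusted p of 1.04e-06 (adjusted p = 0.314 with an estimated correlation). The autophagy receptor Sqstm1 rose by 1.45 (SE 0.07, limma adjusted p = 9.29e-05) and the lysosomal galactosidase Gla by 0.62 (SE 0.07, adjusted p = 0.00221). The 12 lysosomal rises were 5 without Ctrl MO replicate 1, 3 without Ctrl MO replicate 2, 4 without Reg1-MOs replicate 1 and 2 without a variance trend, and the Lamp2 call ended without any 1 of these 3 libraries (adjusted p up to 0.105). Of 21 genes of glycolysis and hypoxia, 7 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 7.97e-05 (adjusted p = 0.314 with an estimated correlation). The glycolytic enzymes Pkm (0.60), Aldoa (0.64) and Pgk1 (0.52) were among them, with 1 rise in the list without a variance trend, where the calls of Aldoa (limma adjusted p = 0.0585) and Pgk1 (0.0595) ended. Gapdh, listed with 7 to 13 reads, gave no usable value but was counted among the 21 genes.

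In iron handling, 6 of 15 genes rose and the ferroxidase Cp (-0.85) and Steap4 (-1.47) fell (7 and 4 adjusted over the list alone). Hmox1, Slc40a1 and the ferritin chains Ftl1 (0.93) and Fth1 (0.75) were among the rises. The list's median was 0.09 and its mean 0.40, and camera gave an adjusted p of 0.0649. This was 0.00115 without Ctrl MO replicate 1, although the median then lay at -0.01, and 1.25e-04 without Ctrl MO replicate 2, with a median of 0.188. Without Reg1-MOs replicate 1 the median was 0.201, and without Reg1-MOs replicate 2 it was 0.0565. Without a variance trend 4 genes rose and 1 fell, and the call of Steap4 ended (limma adjusted p = 0.0595). Of 20 genes of cholesterol synthesis, the 4 that passed all fell, among them Insig1 (-0.43), Hmgcs1 (-0.43) and Acat2 (-0.70), with 5 falls adjusted over the list alone. The list's median was -0.225 and its camera adjusted p 4.78e-04 (adjusted p = 0.44 with an estimated correlation), beside a median of -1.40 for the stromal cell markers in the same libraries. The calls of these 3 genes ended without Ctrl MO replicate 1 (limma adjusted p = 0.0685 for Insig1, 0.0923 for Hmgcs1 and 0.0527 for Acat2), and those of Hmgcs1 (0.0657) and Acat2 (0.0678) also without Reg1-MOs replicate 1. The list had 0 falls without Ctrl MO replicate 1, 1 without Reg1-MOs replicate 1 and 1 without a variance trend.

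Cell cycle genes were lower as a list, with 4 of 26 lower and none higher (4 and 0 adjusted over the list alone), a median of -0.33 and a camera adjusted p of 0.0188 (adjusted p = 0.314 with an estimated correlation). They were Ube2c (-1.21), Ccnb2 (-1.12), Top2a (-0.70) and Birc5 (-1.35), all mitotic genes with means of 18.25 to 202.5 reads. The list's call ended among genes with a mean of at least 50 reads (median -0.215, adjusted p = 0.14) and without Reg1-MOs replicate 2 (0.204). Without Reg1-MOs replicate 1 the calls of Ccnb2 (limma adjusted p = 0.0770) and Top2a (0.0857) ended, and that of Birc5 ended without any 1 library (up to 0.164), leaving 1 fall in the list without Reg1-MOs replicate 1 and 2 without a variance trend. Stromal cell markers, at a median of -1.40, moved the same way in these libraries.

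Among markers of cell types, all 12 stromal and fibroblast markers in the table fell (12 adjusted over the list alone), with a median of -1.40 and a camera adjusted p of 5.45e-12 (adjusted p = 0.314 with an estimated correlation). The most abundant were fibronectin, Fn1 (-1.43), which macrophages also make, Pdgfrb (-0.55) and the collagen genes Col1a2 (-1.63, SE 0.13) and Col1a1 (-1.78, SE 0.13), and the matrix gene Postn fell by 1.59. Of 8 markers of dendritic cells and antigen presentation, Itgax, Ccl22 and the actin bundler Fscn1 (-0.67) fell and none rose (4 and 0 adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 0.00582 (adjusted p = 0.314 with an estimated correlation; median -0.0994 and adjusted p = 0.0415 without Reg1-MOs replicate 1). Of 17 macrophage identity genes, Cebpa (0.56) and Cd68 (0.34) rose and Itgam, Apoe (-0.43) and Lyz2 (-0.27) fell (3 and 7 adjusted over the list alone), with Csf1r at 0.01 (-0.01 without Ctrl MO replicate 1 or Reg1-MOs replicate 2) and a camera adjusted p of 0.256; 5 fell with median-ratio scaling or equal totals. None of 14 neutrophil markers passed (0 adjusted over the list alone; camera adjusted p = 0.208), with Cd177 at -0.60 and Ltf at -0.37 (-0.37 and -0.14 without Reg1-MOs replicate 2, and Ltf -0.59 without Reg1-MOs replicate 1). None of 4 lymphocyte markers passed (2 lower adjusted over the list alone; 0.104), with Ighm at -0.34 and Cd79b at -0.82. Without Reg1-MOs replicate 1 both lists passed, at 0.0171 and 0.0252, and Cd177 passed without Ctrl MO replicate 1 (limma adjusted p = 0.0329). Of mast cell and basophil markers only Kit was in the table and fell by 0.67 (1 adjusted over the list alone), a call that ended without any 1 library (adjusted p up to 0.217), among genes with a mean of at least 50 reads (0.0513), with quantile normalization (0.0573) and with voom weights (0.0516). Of the erythroid markers, Car2 (-0.35, adjusted p = 0.0606) and Epor (0.01, at a mean of 5 reads, and -0.19 or 0.22 without Reg1-MOs replicate 1 or 2) were in the table and did not pass (1 lower adjusted over the list alone). Without either control or Reg1-MOs replicate 1 the calls of Cebpa (up to 0.0857) and Cd68 (up to 0.210) ended, as did that of Apoe without Ctrl MO replicate 1 (0.0814) and that of Lyz2 without any 1 library (up to 0.355) and with quantile normalization (0.0885). Without a variance trend 8 stromal markers fell, and the calls of Pdgfrb (limma adjusted p = 0.0595) and Fscn1 (0.0559) ended. Those of Itgam, Apoe (limma adjusted p = 0.0999), Cd68 and Lyz2 ended there too. Without Ctrl MO replicate 2 the dendritic list had 1 rise. None of the 13 symbols in the list of mitochondrially encoded transcripts was found in the table, so that list was not analysed here.

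**Figure D4:**
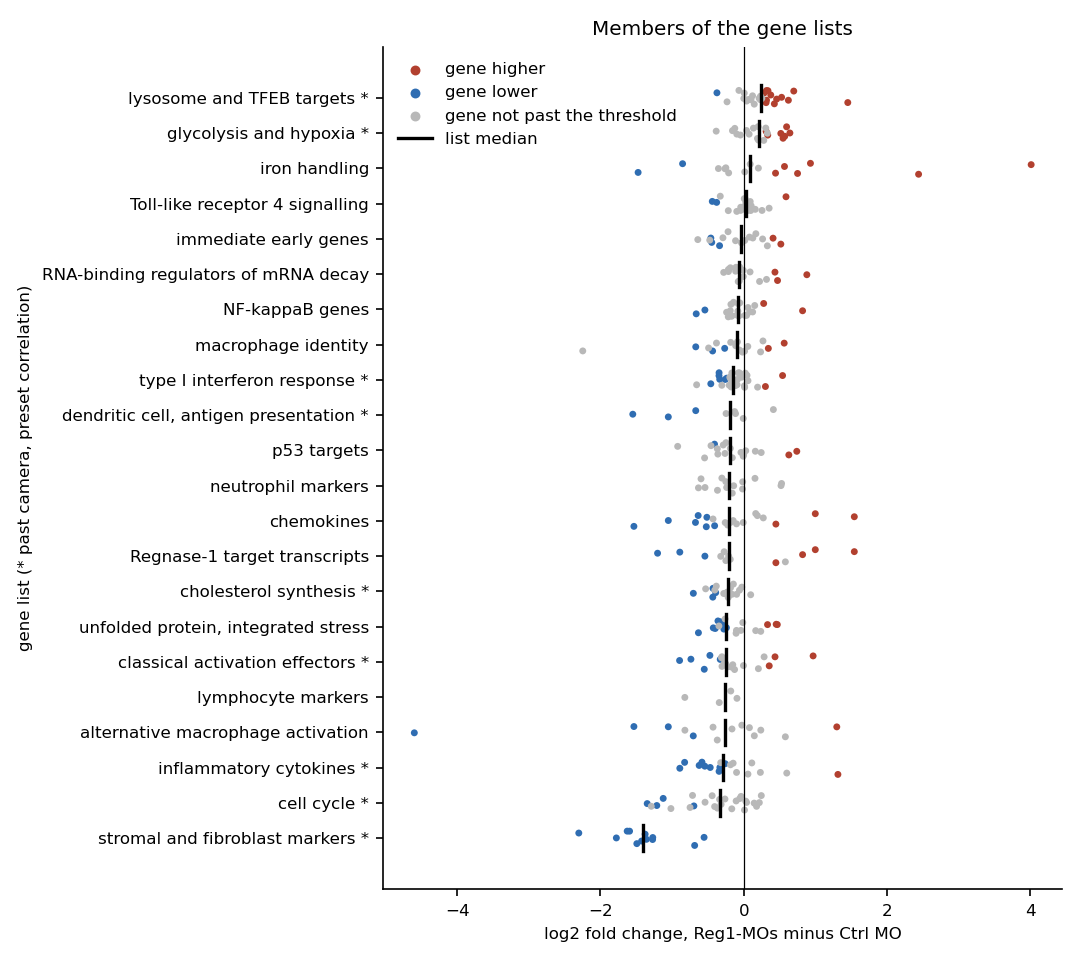
Log2 fold change, Reg1-MOs minus Ctrl MO (horizontal axis), of each member of the 22 tested gene lists (vertical axis, by median); red members rose, blue members fell and grey ones did not pass, bars are list medians, and asterisks mark lists past camera with the preset correlation. Stromal and fibroblast markers lie lowest, with a median of -1.40, and lysosome and TFEB targets highest, at 0.24.

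In all, 9 of the 22 lists passed camera with the preset correlation, 2 higher and 7 lower, and none did with an estimated correlation (lowest adjusted p = 0.314; 2 lists with an unadjusted p under 0.05), while fry called 12. For all 1361 genes past limma's threshold both Reg1-MOs libraries lay on 1 side of both Ctrl MO libraries; this held for 6548 of all genes, or 58.9%, where chance gives 33.3%. The residual ribosomal RNA Rn18s rose by 0.93 in these poly(A) libraries (limma adjusted p = 0.00205). The counts of genes depended on which library was left out: without Ctrl MO replicate 1, 412 genes were higher and 454 lower, without Ctrl MO replicate 2, 393 were higher and 354 lower, without Reg1-MOs replicate 1, 249 were higher and 258 lower, and without Reg1-MOs replicate 2, 530 were higher and 860 lower. Without a variance trend, 195 genes were higher and 182 lower.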

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

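The voom weights were chosen after the data were seen and the other settings before. Without a variance trend 195 genes were higher and 182 lower, against 691 and 670, and 348 of these were called in both. With 1 library left out, which assumes that a lone library varies like the other group, 249 to 530 genes were higher (249 without Reg1-MOs replicate 1) and 258 to 860 lower; in these fits fewer samples remain. A replicate block gave 1532 higher and 1891 lower, all 1361 genes included. That fit leaves fewer residual degrees of freedom than the main fit. With it, 3 interferon genes rose and 17 fell, and 0 cholesterol synthesis genes rose and 12 fell. Iron handling then passed camera (adjusted p = 0.0107). Deviations of same-numbered libraries correlated at 0.314 over 9476 genes, but no label states a pairing and there are only 2 pairs, so whether same-numbered samples share more than a number is not known. Camera with an estimated correlation called 0 lists instead of 9. Calls were also lost where the estimate lay below the preset 0.01. These were classical effectors (-0.028), cell cycle (-0.0222), dendritic markers (-0.02) and glycolysis (-0.0166), while cholesterol synthesis had 0.373. A lost call therefore need not stem from correlation, since that version of camera rests on the 2 residual degrees of freedom. The cause of the other differences was not tested. Other offsets, filters, scalings, a robust trend and voom weights gave 651 to 883 higher and 619 to 704 lower genes. With 1 library left out none of the 1361 called genes could change direction. For all of them both Reg1-MOs libraries lay on 1 side of both Ctrl MO libraries. No gene called both in the main fit and in another setting was reversed in any of the settings. Zc3h12a passed in all of them, with log2 fold changes of 1.05 to 1.14 and a limma adjusted p of at most 0.0292. Of 2105 values of 141 genes, those of the rule and those named besides, 1890 kept direction and side of the threshold, 183 no longer passed, 22 newly passed and 10 turned in sign, all of genes past the threshold in neither fit. Cdkn1a turned to 0.0175 with median-ratio scaling, 0.0213 with equal totals and 0.0347 with quantile normalization. With 1 library left out Cdkn1a lay at -0.0390 to 0.0358, Csf1r at -0.0110 to 0.0342, Epor at -0.188 to 0.218, Rel at -0.558 to 0.181 and Isg15 at -0.0126 to 0.103. edgeR and DESeq2, planned for recovered reads, were not run, as tests of counts were ruled out for values deposited as logs. Of the smallest simulated changes, 7.2% were recovered, all in genes with a mean of at least 50 reads. Depth may limit the genes with fewer reads further, which was not tested.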

Other observations

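The single genes given next are in none of the fixed lists, fall outside the rule and were chosen after their values were seen. The haem transporter gene Slc48a1, also among the 14 NRF2 targets below, rose by 1.35 and the cyclin-dependent kinase inhibitor gene Cdkn2b by 1.54, while the cyclin gene Ccnd2 fell by 1.14 and the scavenger receptor genes Stab2 and Stab1 fell by 1.31 and 0.94. The Cdkn2b call ended without Reg1-MOs replicate 1 or Reg1-MOs replicate 2, and also without a variance trend.

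The tests of the stromal markers and of the pseudogenes were chosen after the results they measure had been seen; those of unseen NRF2 targets and of 3' untranslated regions were chosen after the comparison of the groups but before they were computed.

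All 12 stromal and fibroblast markers in the table were lower with Reg1-MOs, the most abundant being Fn1, which macrophages also make, Pdgfrb and Col1a2 with means of 1394.5, 920.75 and 629.5 reads; 0 of the 12 are in another list, and the labels name no sort or gate. All 12 stayed lower past the threshold under each of the 3 other scalings. Those moved the median over all genes only from -0.0256 to -0.00654, -0.00274 and -0.00704, so the markers could hardly have lost their calls. The values show something narrower. The markers had a median of -1.40 beside -0.0256 over all genes, a gap that 1 scaling factor per library cannot make. Fewer stromal cells in the Reg1-MOs cultures is a candidate explanation: a list of 14 further stromal genes that do not encode matrix had a median of -0.959 (quartiles -1.45 and -0.506), with Cdh11 (-1.50), Prrx1 (-1.51) and Tagln (-1.21) among 9 falls. Cav1 (0.54) and Fgfr1 (0.79) rose, calls that ended without a variance trend and without Reg1-MOs replicate 1. For Cav1 the call also ended without Ctrl MO replicate 2 or Reg1-MOs replicate 2. The other 3 genes, Csrp1 (-0.03), Fap (-0.48) and Tgfb1i1 (-0.59), did not pass. The falls of the 12 markers were also uneven, from -0.55 (Pdgfrb) to -2.30 (Cxcl12). For the list of 14 genes camera gave p = 2.06e-05, and p = 0.0631 with an estimated correlation. A lower output of each stromal cell, and a difference between the wells that were assigned to the groups, stay open, since no library was made without morpholino or without LPS among those analysed here.

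Of 14 targets of NRF2, the transcription factor of the oxidative stress response, whose values had been seen, 13 rose, among them Txnrd1 (0.85), Gclm (1.20), Srxn1 (0.91) and Gclc (0.61), with Nqo1 at 0.56 (limma adjusted p = 0.137). Of 21 further targets listed before their values were looked up, 9 rose, including Pgd (0.66), Taldo1 (0.59) and Abcc1 (0.66), and Ephx1 (-0.50) and Ugdh (-0.34) fell, with a median of 0.243 (camera p = 2.96e-06, and p = 0.144 with an estimated correlation). The calls of Ephx1 (without Ctrl MO replicate 2 or Reg1-MOs replicate 2) and Ugdh (without either control or Reg1-MOs replicate 1) did not hold. Without a variance trend those of Ephx1, Ugdh, Pgd (limma adjusted p = 0.0557), Taldo1 (0.0695) and Prdx1 (0.0595) ended. Reads shared with processed pseudogenes could affect Fth1, Ftl1, Prdx1 and Txn1. Dropping Prdx1 and Txn1 from the unseen list could not move its median, since Prdx1 (0.63) lay above it and Txn1 (0.20) below. The unchanged median of 0.243 therefore cannot decide on shared reads. The values show something narrower. Among the other 19 unseen targets 8 rose and 2 fell, with quartiles of 0.0789 and 0.582. For these 19 camera gave p = 2.98e-05, and p = 0.134 with an estimated correlation. The rises among unseen targets were thus not limited to Prdx1 and Txn1. A response of NRF2 targets as a group may be at work, as a hypothesis. Whether it follows from Regnase-1 or from the morpholinos and their delivery was not tested.

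Transcripts moved both ways while Zc3h12a rose. Decay through stem-loops with a pyrimidine-purine-pyrimidine loop, the kind Regnase-1 is known to bind, was tested over 9074 genes: the 6117 genes with such a loop on a stem of 5 pairs had a mean log2 fold change of -0.0371, at percentile 91.31 of 10000 draws matched on length and GC content (95% of draws from -0.0436 to -0.0360). The genes with this loop were thus not lower than the matched draws. The test cannot decide on decay through such loops. With 6117 of the 9074 genes carrying one, decay of a few of them would hardly move their mean. It also says nothing of single targets. The control, a purine-pyrimidine-purine loop, lay at percentile 2.34, past the lower bound that was set for an effect (a mean of -0.04539 against -0.04535). Whether this came from imperfect matching, from chance or from that loop itself was not tested. Across genes, which are not independent replicates, Spearman's rho of the fold change was -0.168 with the length of the 3' untranslated region and 0.124 with its GC content. These lie between the bounds written before the test for a cause and for none, so the test leaves length and GC content undecided. Nor can a correlation of this kind tell a length-related bias apart from a change in decay of long transcripts.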
